A study of Mus musculus with 6 samples.

How the data were processed

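Transcript abundance was measured by RNA sequencing in 6 libraries titled as mouse ovarian granulosa cells, 3 control and 3 cetylpyridinium chloride (CPC). Groups and replicate numbers came from the titles. Per the labels' protocols, RNA was purified on silica columns and made into libraries with a SMARTER mRNA-seq kit. The labels contradict the titles in part: the same records name SKOV3, a human ovarian cancer line, with transfection of GATA4, and, per the submitters' processing notes, list Bowtie2, RSEM and the human build hg19, with no versions. The files instead hold mouse Ensembl gene identifiers with locations headed GRCm38.p6. These follow the annotation used for counting and do not by themselves identify the cells. Gata4 had 5489, 7276 and 5548 counts in control and 5643, 5159 and 5781 in CPC. Inha, a granulosa cell gene, had 19494 to 44757 counts per library. Since the listed build is human, the aligner and counter that made these files are uncertain. How reads shared by several genes were assigned is not given in the sources used here.

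Each deposited file holds 1 count per gene for 55487 genes with symbol, type, location and exon length, per the file headers. The counts are whole numbers with totals of 19079345 to 23157541 per library, where RSEM would give estimated counts that need not be whole. They were used as deposited. Symbols were taken from the files. Where 1 symbol stood for several identifiers (Ddit3 among the named genes), the identifier with the larger total was used. Counts of genes with near-identical copies are uncertain, such as Fdps, mt-Co2, Olfr810, Hspa8 and ribosomal protein genes, as are those of overlapping and antisense genes, since no source states the strand.

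Genes were filtered with filterByExpr, which left 15000 of 26620 genes with any count. Library sizes were scaled by TMM and the groups compared with edgeR's quasi-likelihood test (robust, no covariate), with Benjamini-Hochberg adjustment over the tested genes at 0.05. Standard errors are the size of the log2 fold change divided by the square root of F. CPM values of single genes are TMM-scaled, and spreads are SDs over 3 libraries. Sums over a list, and the CPM a list lost, are plain CPM without scaling factors. Floors and counts cover counting error only. The smallest mean levels named rest on under 20 counts per library.

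Before the data were examined, 20 gene lists and 7 marker lists of other cell types were fixed, together with the tests, the alternatives and the rule for naming genes. The lists were p53 targets, DNA damage and repair, pro-apoptotic, anti-apoptotic, granulosa cell, steroidogenesis, cumulus and ovulation, cholesterol synthesis and uptake, S phase, mitosis, antioxidant, integrated stress and unfolded protein response, heat shock, nuclear and mitochondrially encoded respiratory genes, glycolysis and hypoxia, inflammatory, interferon, extracellular matrix, and autophagy and lysosome. The marker lists were oocyte, theca and stroma, surface epithelium, endothelium, leukocyte, erythroid and luteal. Some genes stand in more than 1 list. Lists with at least 3 measured members, 25 in all, were tested with camera on voom values at a preset correlation of 0.01, and members were also counted with adjustment over the list alone. Named genes were the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 5 CPM, no overlap between groups and a symbol that is not a predicted gene or pseudogene, up to 4 members per list with the smallest adjusted p, and 14 genes of granulosa function, apoptosis and DNA damage whatever their values. Sesn1, Calr, Srebf2, the oocyte genes below the filter, the plotted genes Msmo1, Mki67 and Lyz2, and the genes of the lists added in the closing section were named after their values were seen. Results for a few genes that the rule selects are not reported here.

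The replicate numbers paired the libraries. Deviations from the group means correlated at 0.626, 0.576 and 0.596 between libraries with equal numbers and at -0.24 to -0.34 between the others, across genes. The pairing comes from the data, since no label says what a number shares. A fit with the replicate number as a block was fixed as an alternative.

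Other alternatives were DESeq2, limma-voom, RLE factors, library size without scaling factors, no filter, a filter of 5 CPM in 3 libraries, an estimated correlation per list, fry, and leaving out each library. Leaving out a replicate number from both groups, blocked list tests with fry or an estimated correlation, and the block with a GC and length correction were added after seeing the data. GC content was computed from the reference annotation for 99.9% of tested genes.

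The edgeR script was tested on simulated counts for the comparison of CPC with control, 14761 genes with 200 changed. It recovered 17.9% of genes changed 1.5-fold, 61.2% of those changed 2-fold and 89.4% of those changed 4-fold, and 14 of its calls (11.1%) were false, against 26 (19.3%) with the replicate block, 43 (24.6%) with DESeq2 and 12 (9.92%) with limma-voom, all above the 5% aimed at. Simulated libraries shared no effect of a replicate number, so the false share with the block does not carry over to these paired libraries. Only 200 genes were changed in simulation, against 39.3% of tested genes called in the data. The adjusted threshold depends on that share, so the recovered shares do not carry over either. The camera script called the changed simulated list and 0 of 20 unchanged ones. Simulated genes were drawn independently, so this does not test camera on lists of correlated genes. The estimated correlation of the mitosis list was 0.928. Software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with matplotlib 3.10.9.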

Results

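RNA sequencing counts were collected from mouse ovarian granulosa cells, the somatic cells that surround the oocyte in a follicle and make its steroid hormones. The 6 libraries were 3 controls given phosphate-buffered saline and 3 exposed to cetylpyridinium chloride (CPC), a cationic quaternary ammonium antiseptic used in mouthwashes. Dose, exposure time and whether the animals or cultured cells were exposed are not given in the sources used here. Total counts per library were 19079345, 23157541 and 22297940 in control 1 to 3 and 22535261, 19837674 and 20840274 in CPC 1 to 3. Pearson correlations of log2 CPM were 0.979 to 0.984 within control, 0.981 to 0.982 within CPC and 0.938 to 0.956 between the groups. The first principal component held 63.3% of the variance and separated the groups. The second held 15.8% and separated replicate numbers. No pair of libraries in a group differed by as little as counting noise, so each counted as 1 sample. Nothing in the labels says that the replicates came from separate animals or cultures, so p-values measure only the spread between these libraries, which may be technical.

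**Figure D1:**
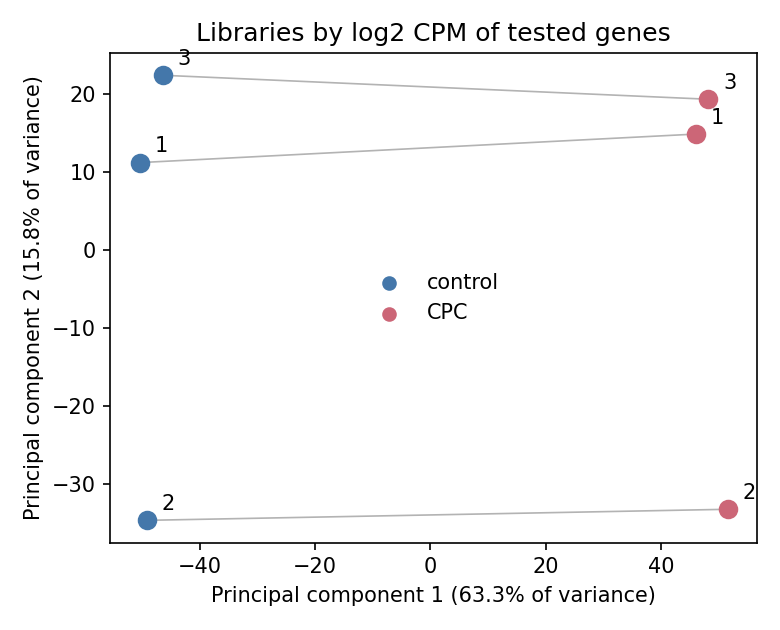
Principal components 1 and 2 of log2 CPM over the tested genes, 1 point per library, coloured by group and numbered by replicate, with grey lines joining equal replicate numbers. Component 1 (63.3% of variance) parts control from CPC, and on component 2 (15.8%) each library lies close to the library of the other group with its number.

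The comparison asked how CPC exposure alters gene expression in granulosa cells, a study aimed at ovarian health that names apoptosis, DNA damage and follicular atresia. CPC libraries had higher expression of stress response genes such as Trib3, Ddit3 and Hspa5 and of p53 target genes such as Gadd45a. They had lower expression of cholesterol synthesis genes, steroidogenic enzymes, granulosa cell genes, cell division genes and macrophage markers. Of 15000 genes tested, 2945 were higher (19.6%) and 2954 lower (19.7%) in CPC by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 1850 changed at least 2-fold, 635 upward and 1215 downward. Of the 5899 changed genes, 5882 had no overlap between the groups' libraries, as had 53.5% of all tested genes, where chance gives 10%. Without control 1 the number of higher genes was 1932. Without replicate 1 of both groups 928 were higher and 1033 lower, and without replicate 2 of both groups 1736 were higher and 1650 lower.

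Coordinates are those of GRCm38.p6, per the file headers. Among the most strongly raised genes was Car6, a secreted carbonic anhydrase (ENSMUSG00000028972; chromosome 4, 150187015 to 150201332), which rose from 0.615 ± 0.73 to 44.4 ± 9.57 CPM (SD, n = 3; log2 change 6.15 ± 0.61, standard error; edgeR adjusted p = 0.00118). Cdsn, which encodes the cornified-envelope adhesion protein corneodesmosin (chromosome 17, 35552128 to 35557180), rose 43.1-fold, from 3.57 ± 2.94 to 154 ± 15.3 CPM. Ptx3, a matrix protein of the expanding cumulus (chromosome 3, 66219910 to 66225805), rose from 1.09 ± 0.504 to 31.4 ± 16.1 CPM, and the scaffold gene Dlg2 (chromosome 7, 90476672 to 92449247) rose 22.4-fold. Trib3, a pseudokinase gene induced by ATF4 and CHOP (chromosome 2, 152337422 to 152344032), rose 12.1-fold, from 32.2 ± 24.1 to 392 ± 56.3 CPM. Ddit3, which encodes CHOP (chromosome 10, 127290774 to 127296288), rose 10.6-fold, from 23.4 ± 14.6 to 248 ± 17.4 CPM. Angptl6, Arhgap33 and Nrip2 rose 13.6-fold, 11.3-fold and 9.65-fold from control levels of 2.29 ± 1.19, 0.942 ± 0.176 and 1.87 ± 0.126 CPM, and Avil, an actin-binding villin family gene, rose 15-fold. Control 3 held the highest control level of several of these: without it the log2 change was 7.81 for Car6, 6.36 for Cdsn, 4.42 for Trib3, 4.03 for Ddit3 and 6.17 for Avil. The Avil call was lost without control 1, CPC 1 or CPC 3 (edgeR adjusted p up to 0.0770) and with no low-count filter (0.0963).

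The largest falls included Abcb1b, a multidrug efflux transporter gene (ENSMUSG00000028970; chromosome 5, 8798147 to 8866315), which fell from 714 ± 380.1 to 29.9 ± 17.5 CPM (SD, n = 3; log2 change -4.58 ± 0.62, standard error; edgeR adjusted p = 0.00322). Pik3c2g, a class II phosphoinositide 3-kinase gene (chromosome 6, 139587221 to 139969284), fell from 99 ± 66.2 to 2.36 ± 1.56 CPM. Mmp12, the macrophage elastase gene (chromosome 9, 7344381 to 7369499), was 44.8-fold lower and Ccl17, a chemokine gene (chromosome 8, 94810453 to 94812036), was 46.2-fold lower. Both were lower in CPC, as were the 11 measured leukocyte markers. The summed level of these (with Cd3e, below the filter) was 201 to 328 CPM in control libraries and 14.3 to 38.7 CPM in CPC libraries. In control 1 to 3 that sum was 201, 254 and 328 CPM. Mmp12 rose along with it at 15.5, 24.4 and 49.8 CPM, and Ccl17 did not, at 20, 10.6 and 17.1 CPM. Apol6 and Lrtm1 were 52-fold and 64.8-fold lower, from 13.9 ± 1.45 and 12.3 ± 3.5 CPM in control. Olfr810 had 534, 187 and 240 counts in control libraries 1 to 3 and 13, 3 and 2 in CPC libraries 1 to 3, and belongs to a family whose members share sequence, so its count is uncertain. Apln, which encodes the peptide apelin, was 30.8-fold lower. Hp, the haptoglobin gene, had 430, 114 and 120 counts in control libraries 1 to 3 and 10, 0 and 0 in CPC libraries 1 to 3. Without control 1 the log2 change was -5.08 for Hp and -5.12 for Olfr810, without control 3 it was -4.74 for Pik3c2g and -4.09 for Apln, without CPC 1, where Hp had 0 counts in both remaining CPC libraries, it was -6.96 for Olfr810, and without CPC 3 it was -5.86 for Apln. With no low-count filter Hp lost its call (edgeR adjusted p = 0.0536).

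**Figure D2:**
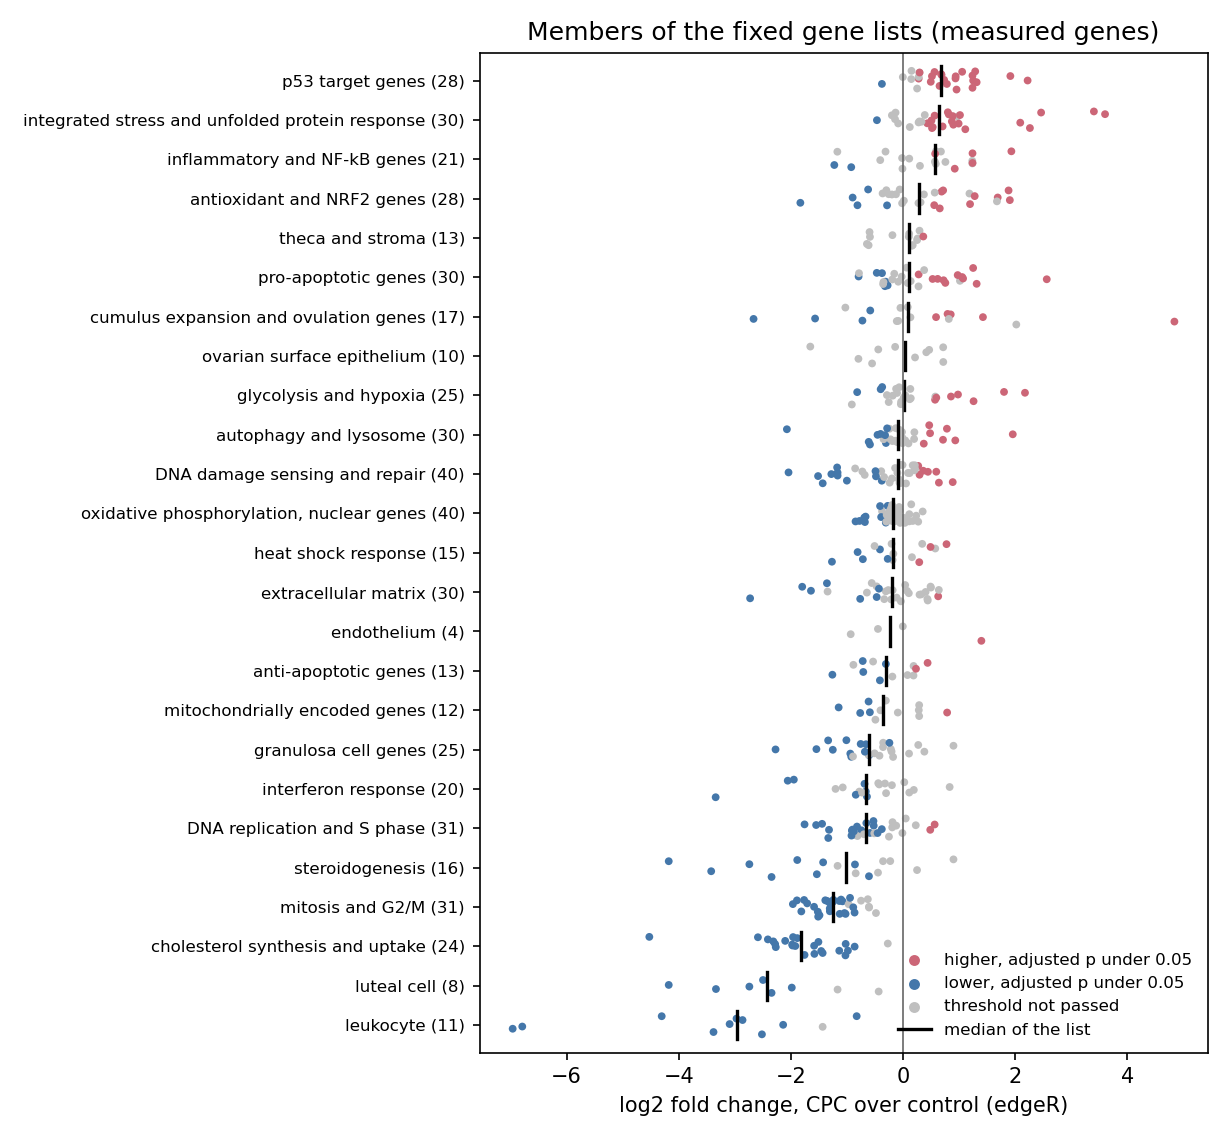
Log2 fold change (CPC over control, edgeR) of every measured member of 25 gene lists, 1 point per gene, with the number measured in brackets, red and blue points past an adjusted p of 0.05 and a black bar at each list's median. The leukocyte, luteal and cholesterol lists have the lowest medians, -2.97, -2.42 and -1.82, and the p53 and integrated stress lists the highest, 0.68 and 0.63.

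Gene lists fixed in advance were tested with camera at a preset inter-gene correlation of 0.01, and 11 of 25 passed an adjusted p of 0.05. None of the 11 passed with an estimated correlation, where adjusted p was 0.56 to 0.87. Splits that mixed the groups gave up to 14 camera calls but 0 changed genes by edgeR (13 to 552 at an unadjusted p under 0.05, 0 to 66 by DESeq2). Each kept part of the group difference and put the rest into the spread within its sides. They therefore do not show what either test gives without a difference. Counts of member genes are given for each list, to be read against the 19.6% of all tested genes that rose and the 19.7% that fell. These counts depend on the libraries. EdgeR gave 4 mitosis falls without replicate 1 or 2 of both groups and 28 without replicate 3. Without replicates 1 and 2 DESeq2 gave 20 and 21, and an unadjusted p under 0.05 gave 22 and 19. Integrated stress rises without replicate 1 numbered 11 by edgeR, 17 by DESeq2 and 18 unadjusted. Where any of these lists is given with 0 rises or 0 falls, DESeq2 and an unadjusted p under 0.05 also gave 0, except for 2 rises of oxidative phosphorylation genes at an unadjusted p and 1 fall of an oocyte gene by DESeq2. Fry, which tests whether a list moves on balance one way, called 11 lists and, with the replicate number as a block, 13.

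Genes activated by the tumour suppressor p53 were higher in CPC. Of 28 measured members 21 rose and 1, Sesn1, fell (22 rose and 1 fell adjusted over the list alone). The 9 members listed, after the results were seen, as also induced by the integrated stress response all rose, with a median log2 change of 1.25. The other 19 had a median of 0.49. Gadd45a, a growth arrest gene (chromosome 6, 67035096 to 67037457), rose from 123 ± 45.9 to 463 ± 76.5 CPM (SD, n = 3; edgeR adjusted p = 0.00296), and Btg2, an antiproliferative gene, rose 2.44-fold, from 180.2 ± 23 to 439 ± 12.9 CPM. Trp53inp1 rose 2.36-fold, from 804 ± 29.6 to 1896 ± 146 CPM. Bbc3, which encodes the BH3-only protein PUMA, rose 2.38-fold, and Sesn2, a stress-inducible sestrin, rose 1.91-fold. Cdkn1a, which encodes the cell cycle inhibitor p21 (chromosome 17, 29090976 to 29100727), rose from 535 ± 116 to 889 ± 78.7 CPM. Mdm2, the p53 ubiquitin ligase gene, rose 1.41-fold and Bax, the mitochondrial pore gene, rose 1.21-fold. The median log2 change of the list was 0.68 (camera adjusted p = 8.32e-08; adjusted p = 0.56 with an estimated correlation; fry adjusted p = 0.00656). Mdm2 lost its call without control 3, CPC 1 or CPC 3 (edgeR adjusted p up to 0.0822). Bax lost it without any library but CPC 2 (up to 0.0980) and with no low-count filter (0.0522). With the replicate block both kept the call (edgeR adjusted p = 7.75e-04 and 0.0117). The fall of Sesn1 was lost without control 2, control 3, CPC 1 or CPC 2.

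DNA damage sensing and repair genes went both ways, with 7 of 40 higher and 11 lower, in number the same adjusted over the list alone. Atr, the replication stress kinase gene, rose 1.85-fold, from 48.6 ± 2.34 to 89.8 ± 5.14 CPM (SD, n = 3), and the mismatch repair gene Msh6 rose 1.51-fold. Clspn, which encodes the checkpoint adaptor claspin, was 4.12-fold lower and the replication ligase gene Lig1 fell from 30.2 ± 5.2 to 15.1 ± 2.67 CPM. H2ax, the histone variant gene whose protein is phosphorylated at DNA breaks (chromosome 9, 44334694 to 44336077), had 18.7 ± 2.17 CPM in control and 14.4 ± 1.4 CPM in CPC (edgeR adjusted p = 0.0487), and its call was lost without any 1 of the 6 libraries (adjusted p up to 0.143) and with DESeq2 (0.0576), limma-voom (0.0511), library size scaling (0.107) or no low-count filter (0.0679). With the replicate block H2ax kept its call (edgeR adjusted p = 0.0222). The list as a whole passed neither camera (adjusted p = 0.388) nor fry (adjusted p = 0.509). Rising members numbered 4 without control 1 or CPC 1, and falling members 6 without control 1 or control 2, 3 without replicate 1 of both groups and 2 without replicate 2 of both.

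Pro-apoptotic genes had 11 of 30 members higher and 6 lower (12 and 6 adjusted over the list alone). Hrk, a BH3-only gene, rose 5.91-fold, from 0.821 ± 0.0864 to 4.89 ± 0.198 CPM (SD, n = 3; edgeR adjusted p = 3.84e-04). Dapk1, a death-associated kinase gene, rose 1.53-fold and Diablo, which encodes an antagonist of apoptosis inhibitors, rose 2.1-fold. Of 13 measured anti-apoptotic genes 5 fell and 2 rose, in number the same adjusted over the list alone. Mcl1, a short-lived survival protein of the Bcl-2 family, fell from 289 ± 19.9 to 177 ± 16 CPM, Cflar, which encodes the caspase-8 inhibitor c-FLIP, fell from 77.7 ± 11.4 to 47.2 ± 3.23 CPM, Bag3 was 1.24-fold lower and Birc2 rose 1.35-fold. Bcl2 (chromosome 1, 106538178 to 106714274) had 10.7 ± 2.57 CPM in control and 7.35 ± 1.03 CPM in CPC (edgeR adjusted p = 0.0837, and 0.0346 without control 2). Camera called neither list (adjusted p = 0.265 for both), while fry gave adjusted p = 0.00656 upward for the pro-apoptotic list (0.0169 with the replicate block) and 0.0263 downward for the anti-apoptotic list (0.113 with the block). Pro-apoptotic rises numbered 7 without control 1, control 2 or CPC 1, and falls 3 without control 1 or control 2, 1 without CPC 1 and 2 without CPC 2. Anti-apoptotic falls numbered 3 without control 1 and 2 without CPC 1, rises 1 without any library but CPC 1, and Bag3 lost its call without CPC 1 or CPC 2 (adjusted p up to 0.0654).

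Integrated stress and unfolded protein response genes rose together: 19 of 30 members were higher and 1, Calr, lower (21 and 1 adjusted over the list alone). Hspa5, the endoplasmic reticulum chaperone BiP, rose 4.8-fold, from 981 ± 32 to 4708 ± 560.0 CPM (SD, n = 3; edgeR adjusted p = 1.99e-04). Ppp1r15a, which encodes the phosphatase subunit GADD34, rose 4.26-fold, from 71.5 ± 10.02 to 304 ± 30.9 CPM. The serine synthesis gene Phgdh rose 2.16-fold and the mitochondrial folate gene Shmt2 rose 1.63-fold. Over all 30 members, which include Ddit3 and Trib3, the median log2 change was 0.63. Camera gave adjusted p = 3.10e-07, camera with an estimated correlation adjusted p = 0.56 and fry adjusted p = 0.00223.

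Other stress lists had members going both ways, where 19.6% of all tested genes rose and 19.7% fell. Of 28 antioxidant and NRF2 genes 9 rose and 5 fell (10 and 6 adjusted over the list alone). Txnrd1, the thioredoxin reductase gene, rose from 382 ± 52.6 to 874 ± 95.8 CPM (SD, n = 3), Abcc1, a glutathione conjugate exporter, rose 2.42-fold and Gclc, the glutathione synthesis enzyme, rose 1.64-fold, while G6pdx, the entry enzyme of the pentose phosphate pathway, fell from 195 ± 10.01 to 111 ± 13.3 CPM. Camera did not call this list (adjusted p = 0.37). With the replicate block 15 members rose and fry gave adjusted p = 0.0169 upward, and rises numbered 4 without control 1 and 5 without control 2. Of 15 heat shock genes 3 rose and 5 fell, in number the same adjusted over the list alone (camera adjusted p = 0.265). Hspa8, the constitutive cytosolic HSP70 gene, fell from 1239 ± 122 to 514 ± 114 CPM, its partners Dnaja1 and Hsph1 were 1.75-fold and 1.64-fold lower, and the small chaperone gene Hspb8 rose 1.71-fold. Heat shock rises numbered 1 without control 1, control 2, CPC 1 or CPC 3. Autophagy and lysosome genes had 7 of 30 higher and 8 lower, in number the same adjusted over the list alone (camera adjusted p = 0.788). Npc1, the lysosomal cholesterol exporter, rose 3.88-fold, from 125 ± 25.7 to 485 ± 149 CPM, Gaa, the acid glucosidase gene, rose 1.64-fold, Gabarapl1 rose 1.38-fold and Gabarapl2 was 1.51-fold lower. Falling autophagy and lysosome genes numbered 5 without control 2 or CPC 1 and 4 without CPC 2.

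Cholesterol synthesis and uptake genes fell almost as a whole, 23 of 24 measured members (24 adjusted over the list alone). Hmgcs1, the synthase upstream of HMG-CoA reductase, fell from 639 ± 119 to 128 ± 12 CPM (SD, n = 3; edgeR adjusted p = 2.05e-04). Insig1, the sterol-sensing retention protein, fell from 65.9 ± 8.34 to 19.5 ± 0.353 CPM and Sc5d, the lathosterol oxidase, was 2.03-fold lower. The median log2 change was -1.82 (camera adjusted p = 2.49e-13; adjusted p = 0.56 with an estimated correlation; fry adjusted p = 0.00628). The 1 member that did not pass with adjustment over all genes was Srebf2, the sterol-responsive transcription factor gene, named here after its value was seen, with a log2 change of -0.27 ± 0.099 (standard error). The leukocyte markers fell in the same libraries, from 201 to 328 CPM summed over the markers in control to 14.3 to 38.7 CPM in CPC.

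Granulosa cell genes were lower in CPC: 12 of 25 measured members fell and 0 rose (14 and 0 adjusted over the list alone). Inhbb, which encodes an activin and inhibin subunit, fell from 174 ± 17.4 to 36 ± 3.08 CPM (SD, n = 3; edgeR adjusted p = 8.55e-05). Igf1, the insulin-like growth factor gene, fell from 465 ± 92.6 to 159 ± 26 CPM, Cdh2, which encodes N-cadherin, was 2.02-fold lower and Fst, the activin antagonist follistatin, was 2.52-fold lower. Foxl2, the transcription factor gene that keeps granulosa identity (chromosome 9, 98955288 to 98958543), fell from 68.9 ± 15.1 to 35.9 ± 6.77 CPM. Fshr, the follicle-stimulating hormone receptor gene (chromosome 17, 88984952 to 89200675), fell from 3.25 ± 0.582 to 1.36 ± 0.156 CPM. Inha, the inhibin alpha gene (chromosome 1, 75507077 to 75510366), was 1.52-fold lower. Gata4 (chromosome 14, 63198922 to 63271692) had 290.4 ± 28.3 CPM in control and 257 ± 14 CPM in CPC (edgeR adjusted p = 0.171). The median log2 change was -0.61 (camera adjusted p = 2.27e-04; adjusted p = 0.621 with an estimated correlation; fry adjusted p = 0.0164). The leukocyte markers fell in the same libraries (201 to 328 CPM summed in control, 14.3 to 38.7 CPM in CPC). Summed granulosa cell genes went from 11678 to 7045, 12487 to 8891 and 10613 to 7331 CPM in replicates 1 to 3. The list as a sum thus lost far more CPM than the leukocyte markers held. The block gave 17 falls and 1 rise, and an edgeR adjusted p of 0.0051 for Inha. Inha lost its call with library size scaling (edgeR adjusted p = 0.0544) and without any library but CPC 3 (up to 0.113), and Amh, the anti-Mullerian hormone gene, had 4 counts in all in each group, too few to test.

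Steroid hormone synthesis genes fell with them, 9 of 16 measured members with 0 rising (10 and 0 adjusted over the list alone). Cyp11a1, the cholesterol side-chain cleavage enzyme, fell from 5365 ± 1507 to 1056 ± 439.7 CPM (SD, n = 3; edgeR adjusted p = 0.00263). Hsd3b1, which makes progesterone, fell from 2799 ± 454 to 419 ± 149 CPM, the electron carrier gene Fdx1 was 2.69-fold lower and Hsd17b12 was 1.81-fold lower. Star, the mitochondrial cholesterol import gene (chromosome 8, 25806555 to 25815982), had 1067 ± 591 CPM in control and 475 ± 214 CPM in CPC (edgeR adjusted p = 0.107), and with the replicate block its log2 change was -1.12 ± 0.092 (standard error; adjusted p = 2.99e-05). Cyp19a1, the aromatase gene (chromosome 9, 54165937 to 54268110), was at 0.487 ± 0.107 CPM in control and 0.92 ± 0.402 CPM in CPC (edgeR adjusted p = 0.122). The list's median log2 change was -1.01 (camera adjusted p = 2.27e-04; adjusted p = 0.621 with an estimated correlation; fry adjusted p = 0.0166). Luteal cell markers, several of them steroidogenic, fell in 6 of 8 cases (7 adjusted over the list alone), with 0 rising. Prlr, the prolactin receptor gene, fell from 153 ± 23.8 to 27.1 ± 7.53 CPM and Sfrp4, a secreted Wnt antagonist, was 3.96-fold lower, and the median was -2.42 (camera adjusted p = 3.01e-04; adjusted p = 0.56 with an estimated correlation; fry adjusted p = 0.0068). Without CPC 1, 1 steroidogenesis gene rose.

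Cumulus expansion and ovulation genes did not move as a list (camera adjusted p = 0.713; median log2 change 0.08). Of 17 measured, 5 rose and 4 fell, in number the same adjusted over the list alone. Besides Ptx3, Ptgs2, the inducible prostaglandin synthase gene, rose from 133 ± 30.3 to 357 ± 98.5 CPM (SD, n = 3) and Tnfaip6, a hyaluronan-binding protein gene, rose 1.8-fold. Has2, the hyaluronan synthase gene, fell from 3.77 ± 1.54 to 0.591 ± 0.167 CPM. Rises numbered 3 without any control library or CPC 3, and falls 2 without CPC 1.

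Cell division genes were lower in CPC. Of 31 genes of DNA replication and S phase 19 fell and 2 rose (20 and 2 adjusted over the list alone). Rrm2, the small subunit of ribonucleotide reductase, fell from 60.4 ± 6.84 to 17.9 ± 1.99 CPM (SD, n = 3; edgeR adjusted p = 2.24e-04) and its large subunit gene Rrm1 was 1.57-fold lower, while the helicase subunit gene Mcm2 rose 1.48-fold. Of 31 genes of mitosis and G2/M 25 fell and 0 rose (28 and 0 adjusted over the list alone). The mitotic kinesin gene Kif20a fell from 35 ± 11.6 to 8.94 ± 2.42 CPM, the mitotic kinase gene Plk1 fell from 18.2 ± 5.25 to 5.55 ± 1.66 CPM, and Racgap1 and Kif2c were 2.48-fold and 3.71-fold lower. Median log2 changes were -0.66 for the S phase list (camera adjusted p = 5.92e-05; adjusted p = 0.621 with an estimated correlation; fry adjusted p = 0.0373) and -1.24 for the mitosis list (camera adjusted p = 1.37e-07; adjusted p = 0.621 with an estimated correlation; fry adjusted p = 0.0764, and 0.0321 with the replicate block). The number of falling mitosis genes was 11 without control 1, 10 without control 2 and 15 without CPC 2. S phase rises numbered 1 without any library but control 2. The leukocyte markers fell in the same libraries (201 to 328 CPM summed in control, 14.3 to 38.7 CPM in CPC).

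**Figure D3:**
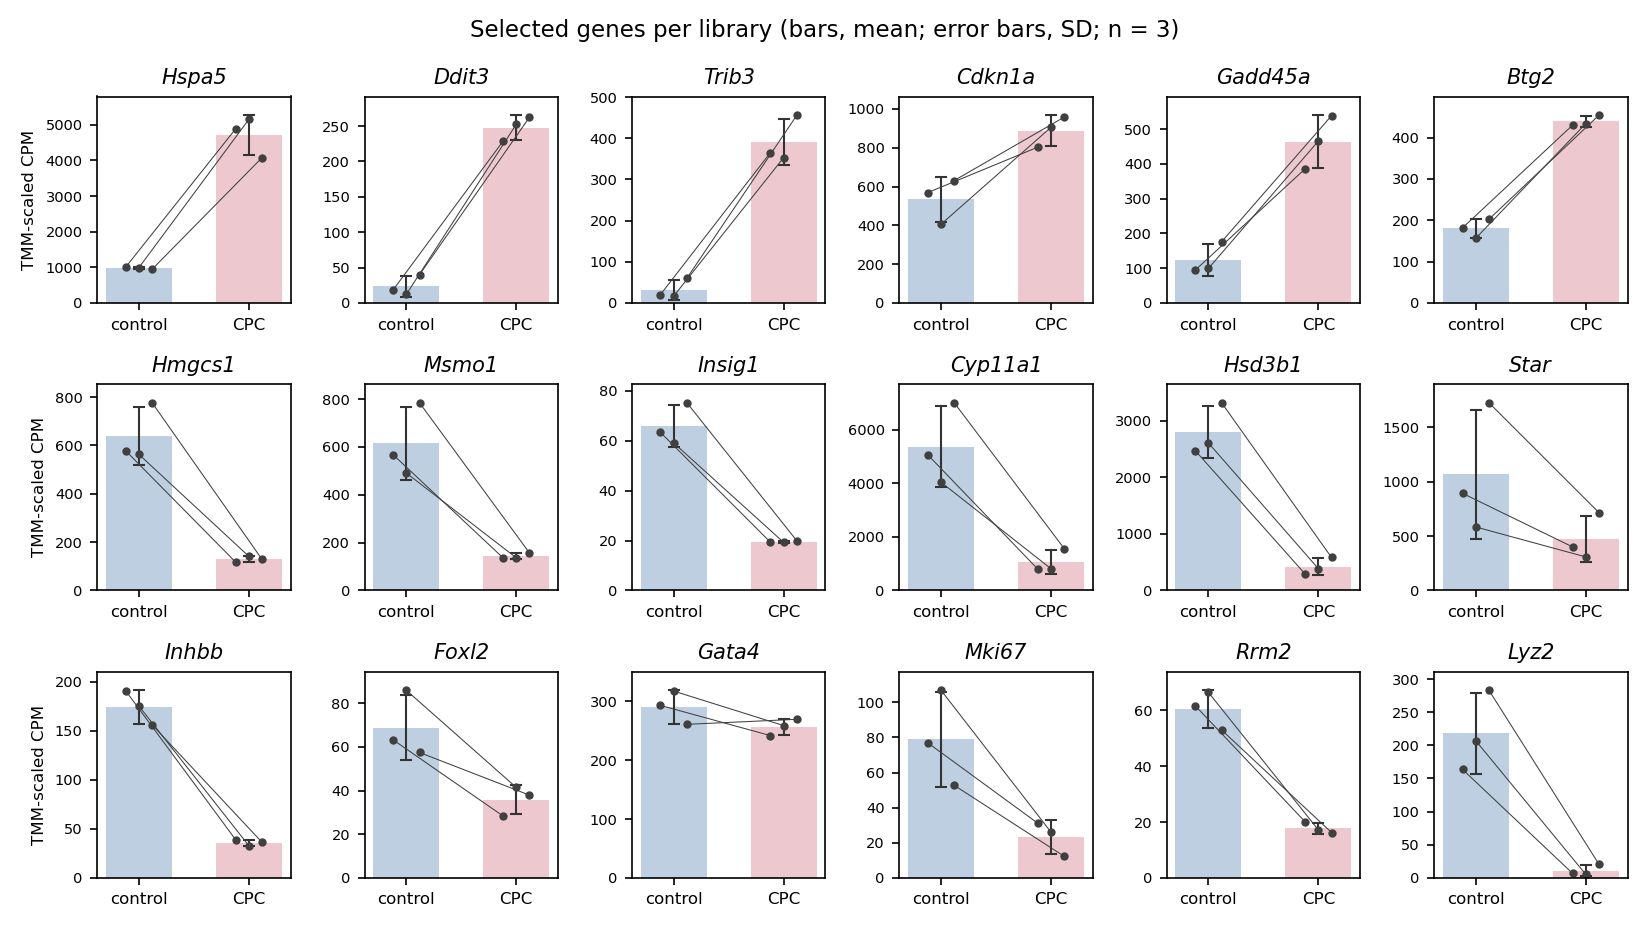
TMM-scaled CPM of 18 genes per library, with bars at the group mean, error bars of 1 SD (n = 3), points for libraries and lines joining equal replicate numbers; each panel has its own axis from 0. Hspa5, Ddit3, Trib3, Cdkn1a, Gadd45a and Btg2 were higher in every CPC library than in every control library, while Gata4 overlapped between the groups and Star fell within each replicate number but overlapped between groups.

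Energy metabolism lists had small median changes. Of 40 nuclear genes of oxidative phosphorylation 10 fell and 0 rose (9 and 0 adjusted over the list alone). Ndufa4 fell from 123 ± 14.1 to 68.1 ± 5.16 CPM (SD, n = 3), and Uqcrfs1, Ndufb3 and Sdhd were 1.6-fold, 1.62-fold and 1.31-fold lower. The median log2 change was -0.19 (camera adjusted p = 0.00708; adjusted p = 0.873 with an estimated correlation; fry adjusted p = 0.191), camera lost the call without control 3 (adjusted p = 0.113) or CPC 1 (adjusted p = 0.0703), and with the replicate block 19 members fell and 3 rose, and falls numbered 6 without CPC 1 or CPC 2. Without control 3, 2 members rose. Of 12 measured mitochondrially encoded genes 4 fell and 1 rose, in number the same adjusted over the list alone (camera adjusted p = 0.164; fry adjusted p = 0.0373 downward). mt-Nd5 fell from 7172 ± 532 to 4221 ± 379 CPM, mt-Nd1 was 1.51-fold lower, and mt-Nd6, which lies on the light strand, was 2.22-fold lower. mt-Co2 rose 1.72-fold, but nuclear copies of mitochondrial genes make its count uncertain, and its call was lost with the block (edgeR adjusted p = 0.0853), without any library but CPC 3 (up to 0.0887) and with no low-count filter (0.124). Glycolysis and hypoxia genes had 7 of 25 higher and 3 lower, in number the same adjusted over the list alone (camera adjusted p = 0.692). Vegfa, the vascular growth factor gene, rose 4.51-fold, from 174 ± 47.7 to 785 ± 30.7 CPM, the hypoxia-inducible gene Ndrg1 rose 3.48-fold, Pdk1 rose 1.81-fold and the pyruvate kinase gene Pkm fell from 699 ± 56.4 to 396 ± 15.6 CPM. Rises in that list numbered 4 without control 2, control 3 or CPC 1, and falls 5 with the block.

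Inflammatory and NF-kB genes had 5 of 21 measured members higher and 2 lower, in number the same adjusted over the list alone (camera adjusted p = 0.146). Relb, an NF-kB subunit gene, rose from 9.95 ± 0.559 to 23.5 ± 1.22 CPM (SD, n = 3), the adhesion gene Icam1 rose 1.89-fold, the chemokine gene Cxcl2 rose 3.81-fold and the prostaglandin E synthase gene Ptges fell from 309 ± 44.9 to 132 ± 20.03 CPM. With the replicate block 10 members rose, without control 1 camera gave adjusted p = 0.0465, and falls numbered 1 without control 1, control 2, CPC 1 or CPC 3. Interferon response genes were lower in 7 of 20 cases with 0 rising (6 and 0 adjusted over the list alone). Stat2, the interferon signalling factor gene, fell from 26.8 ± 1.12 to 14.9 ± 1.5 CPM, Bst2, which encodes tetherin, was 1.61-fold lower, and Cmpk2 and Rtp4 were 10.1-fold and 4.16-fold lower from low control levels. Their median was -0.65 (camera adjusted p = 0.0129; adjusted p = 0.621 with an estimated correlation; fry adjusted p = 0.0795, and 0.0169 with the block). Camera lost this call without control 2 (adjusted p = 0.0530), without CPC 3 (adjusted p = 0.0707) and with the stricter filter (adjusted p = 0.0915). With the block 10 members fell and 1 rose, and Bst2 and Rtp4 kept their calls (edgeR adjusted p = 4.36e-05 and 0.00138). Falls numbered 4 without control 1 or control 2, 3 without CPC 1 and 2 without CPC 3, and Bst2 and Rtp4 lost their calls without CPC 1 or CPC 3 (edgeR adjusted p up to 0.0770 and 0.0611).

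Extracellular matrix genes had 1 of 30 higher and 7 lower (1 and 4 adjusted over the list alone; camera adjusted p = 0.265). The falling members were mostly proteases and their inhibitors: Timp1 fell from 84.3 ± 21.8 to 27 ± 2.27 CPM (SD, n = 3), Timp2 was 1.7-fold lower and Mmp9 was 6.63-fold lower from 1.87 ± 0.907 CPM in control. The laminin gene Lamb1 rose 1.54-fold. With the replicate block 5 rose and 11 fell. Falls numbered 3 without control 1 and 4 without control 3, CPC 2 or CPC 3, rises 4 without CPC 3, where the list turned upward (camera adjusted p = 0.973), and camera called the list downward without CPC 1 (adjusted p = 0.0190). Mmp9 and the interferon genes fell in the libraries in which the leukocyte markers fell, 201 to 328 CPM summed in control against 14.3 to 38.7 CPM in CPC.

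Markers of other cell types were measured in the same libraries. Leukocyte markers, mostly of macrophages, fell in 10 of 11 cases (11 adjusted over the list alone), with a median log2 change of -2.97 (camera adjusted p = 1.37e-06; adjusted p = 0.56 with an estimated correlation; fry adjusted p = 0.00628). Csf1r, the macrophage growth factor receptor gene, fell from 8.58 ± 2.26 to 1.09 ± 0.258 CPM (SD, n = 3) and Adgre1, which encodes F4/80, was 10.4-fold lower. The complement gene C1qa had 38, 63 and 67 counts in control libraries 1 to 3 and 1, 0 and 0 in CPC libraries 1 to 3, and C1qb had 39, 56 and 54 counts in control libraries 1 to 3 and 0, 0 and 1 in CPC libraries 1 to 3. Theca and stroma markers had 1 of 13 higher, the hedgehog receptor gene Ptch1 (1.28-fold; call lost without control 1, edgeR adjusted p = 0.0555; 2 markers higher without CPC 3), and endothelial markers 1 of 4, Esam (2.63-fold; lost without control 2, control 3 or CPC 1, up to 0.0746), with 0 falls in either and in number the same adjusted over the list alone. Mfap5, Nr2f2 and Col3a1 of the stroma list had log2 changes of -0.61 ± 0.43, 0.11 ± 0.090 and -0.64 ± 0.61, and Kdr, Pecam1 and Tek of the endothelial list of -0.93 ± 0.62, -0.45 ± 0.40 and 0.00 ± 0.36 (standard errors), none of which passed. Of 10 ovarian surface epithelium markers 0 passed edgeR, also adjusted over the list alone: Krt8 had 98.5 ± 32 CPM in control and 67 ± 46 CPM in CPC and Epcam 4.09 ± 1.11 CPM in control and 6.7 ± 2.26 CPM in CPC, and Muc16 and Upk1b had log2 changes of -1.65 ± 1.08 and -0.80 ± 1.30. With the replicate block 4 epithelial markers fell and 1 rose, 2 stromal markers fell and 1 endothelial marker fell: Epcam rose (log2 change 0.69) and Krt8 (-0.70), Muc16 (-1.89), Upk1b (-1.17), Col3a1 (-0.85) and Kdr (-1.01) fell (edgeR adjusted p up to 0.0473). Without CPC 1 log2 changes were -3.20 for Muc16, -3.09 for Upk1b, -1.82 for Kdr, -1.60 for Col3a1 and -1.27 for Krt8, the last 2 past the threshold (edgeR adjusted p = 0.0194 and 0.0231), and the epithelial median was -2.40. Without CPC 2 Epcam rose (0.0385). Summed epithelial markers went from 412 to 473, 159.7 to 98.3 and 182.8 to 107.6 CPM from control to CPC in replicates 1 to 3. The epithelial median was 0.72 without control 1 and -0.77 without replicate 1 of both groups, against 0.04 with all libraries. Camera adjusted p was 0.901, 0.788 and 0.993 for the stromal, epithelial and endothelial lists.

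Germ cell and blood markers were near the limit of detection. Of 14 oocyte markers 2 passed the count filter, Kit at 1.33 ± 0.21 CPM in control and 1.0 ± 0.314 CPM in CPC (SD, n = 3) and Sycp3 at 0.737 ± 0.109 CPM in control and 0.688 ± 0.395 CPM in CPC, and 0 passed edgeR, also adjusted over the list alone. Without control 1, 2 members fell, and without CPC 2 or CPC 3, 1 fell. Below the filter, Zp2, a zona pellucida gene, had 54 counts over the 3 control libraries and 0 over the CPC libraries. Nlrp5 had 24 and 1, Zp3 had 18 and 2 and the oocyte growth factor gene Gdf9 had 43 and 14. Ddx4 had 20 and 12, Nobox was level at 2 and 2, and Dazl went the other way with 6 and 11. None of the 7 erythroid markers was measured.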

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

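Alternatives added after seeing the data were those leaving out a replicate number from both groups, the blocked fry and estimated-correlation tests and the block with GC correction. DESeq2, RLE factors, limma-voom and the replicate block kept the counts of genes higher, lower and changed 2-fold within 1.5 times of 2945, 2954 and 1850, and no setting called a gene in the opposite direction. DESeq2 called 2881 higher and 3024 lower. Scaling by library size alone made 59.3% of calls upward, against 49.9%. The stricter filter, which tests fewer genes, left 959 genes changed at least 2-fold. Leaving out 1 library gave 1932 to 2613 higher, 2047 to 2576 lower and 1564 to 1805 changed 2-fold. Without replicate 1 of both groups the counts were 928, 1033 and 1072, and without replicate 2 of both groups 1736 were higher and 1650 lower, with fewer samples in each. The replicate block gave 3978 higher and 4178 lower, and apart from the calls and member counts given with their results it changed no other call of a list or named gene and moved no other count of list members by over 1.5 times.

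Of the list tests, an estimated correlation ended all 11 camera calls: adjusted p was 0.560 for the p53, cholesterol, integrated stress, leukocyte and luteal lists, 0.621 for the granulosa, steroidogenesis, S phase, mitosis and interferon lists and 0.873 for oxidative phosphorylation. With the replicate block and an estimated correlation these were 0.504, except 0.554 for S phase and 0.737 for oxidative phosphorylation. Fry gave 0.00656 for pro-apoptotic, 0.0263 for anti-apoptotic and 0.0373 for mitochondrially encoded genes, now past the threshold, and 0.0764 for mitosis, 0.191 for oxidative phosphorylation and 0.0795 for interferon genes, no longer past it. Blocked fry gave 0.0169 for pro-apoptotic and antioxidant genes, 0.0483 for mitochondrially encoded genes and 0.113 for oxidative phosphorylation. With no filter the mitochondrially encoded list reached 0.0251, and with the stricter filter the interferon list gave 0.0915. Without replicate 1 of both groups oxidative phosphorylation gave 0.0662. The estimated correlation widens the variance of correlated genes and leaves fewer degrees of freedom, and fry tests another null hypothesis; apart from these the cause was not tested. Counts of list members also moved with no low-count filter (13 falls of mitosis genes, 4 rises of antioxidant genes, 2 rises of extracellular matrix genes, 3 falls of oocyte genes, and 1 anti-apoptotic rise and 1 inflammatory fall), with library size scaling (3 pro-apoptotic and 5 autophagy falls, 8 inflammatory, 3 extracellular matrix and 2 oxidative phosphorylation rises), with DESeq2 (3 extracellular matrix rises) and with the stricter filter, which tests fewer genes (4 interferon and 3 leukocyte falls). Leaving out replicate 1, 2 or 3 of both groups moved a count by over 1.5 times in 22, 15 and 11 of 25 lists. Without replicate 1 there remained 4 mitosis, 6 S phase, 4 granulosa, 5 steroidogenesis, 2 oxidative phosphorylation, 2 interferon, 3 DNA damage and 1 autophagy falls and 11 integrated stress and 13 p53 rises, and without replicate 2 there remained 2 DNA damage, 4 mitosis, 9 S phase, 6 oxidative phosphorylation and 3 autophagy falls, with mitosis medians of -1.43 and -1.07 and fewer samples in each. Of the pro-apoptotic falls edgeR kept 0 in both (4 and 4 at an unadjusted p under 0.05, 1 and 1 by DESeq2). In the same settings DESeq2 kept 20 and 21 mitosis falls and 13 and 11 S phase falls.

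Directions changed only for lists and genes that did not pass the threshold in the main tests: theca and stroma with library size scaling (0.981), without replicate 1 of both groups (0.781) and with blocked fry (0.965), endothelium with fry (0.872), blocked fry (0.965) and without replicate 2 of both groups (0.797), cumulus genes with blocked fry (0.965), and autophagy genes with fry (0.963). Tek was at log2 changes of 0.0580 with library size scaling, 0.00750 with no filter, 0.0420 with limma-voom, 0.0381 with the block, 0.0407 with the block and GC correction and 0.27 without replicate 2 of both groups, and Sycp3 at 0.29 without replicate 1 of both groups. When 1 library was left out, the direction also turned for extracellular matrix genes (0.973 without CPC 3), epithelial markers (0.751 without control 1 and 0.733 without CPC 2), autophagy genes (without control 3 or CPC 2), stromal markers (without control 3 or CPC 1) and endothelial markers (without any library but control 1 or CPC 1), Tek spanned -0.18 to 0.43, Sycp3 -0.64 to 0.24 and Upk1b -3.09 to 0.19. Camera adjusted p without 1 library spanned 2.12e-04 to 0.113 for the oxidative phosphorylation list, 9.07e-04 to 0.0707 for the interferon list, 0.0465 to 0.331 for the inflammatory list, 0.0190 to 0.973 for the extracellular matrix list, 0.457 to 0.998 for the autophagy list, 0.335 to 0.956 for the stromal list, 0.157 to 0.973 for the epithelial list and 0.825 to 0.988 for the endothelial list.

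Of 131 named genes 114 passed the threshold, and 11 of these lost it when some library was left out, 29 without replicate 1 of both groups, 13 without replicate 2 of both and 8 without replicate 3 of both, with fewer samples in each. The replicate block kept all but 1 of the 114 past the threshold and added 7 named genes. Depth limits genes with few counts, such as those of the oocyte, most of which were not testable. In simulation with 3 libraries per group 17.9% of 1.5-fold changes were recovered, and whether depth or the number of libraries sets that share was not tested.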

Other observations

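The lists in this part and the tests on leukocyte transcripts, on part of the liver X receptor list and on p53 targets shared with the stress response were chosen after the results they bear on were seen. Genes of the translation apparatus rose in CPC. Of 35 measured cytosolic ribosomal protein genes 29 rose and 0 fell (33 adjusted over the list alone), with a median log2 change of 0.58, Rpl12 from 283.3 ± 36.6 to 602 ± 54.4 CPM and Rps6 from 322 ± 18.6 to 517 ± 48.1 CPM (SD, n = 3). Their counts are uncertain because many near-identical pseudogenes exist. Of 20 aminoacyl-tRNA synthetase genes 11 rose and 0 fell (12 and 1 adjusted over the list alone), with a median of 0.45. Vars rose from 74.5 ± 6.22 to 157.2 ± 8.28 CPM and Eprs from 391.9 ± 53.4 to 887 ± 31.1 CPM. Camera adjusted p was 3.37e-11 for the ribosomal and 3.43e-05 for the synthetase list (adjusted p = 0.37 for both with an estimated correlation).

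Fatty acid synthesis genes fell, 10 of 13 with 0 rising (11 adjusted over the list alone), with a median log2 change of -1.04. Scd2, a stearoyl-CoA desaturase gene, fell from 3413 ± 561 to 652 ± 127.8 CPM (SD, n = 3), Fasn, the fatty acid synthase gene, from 217 ± 9.38 to 98.7 ± 5.51 CPM, and Fads2, a fatty acid desaturase gene, from 106.7 ± 27.9 to 39.5 ± 3.97 CPM (camera adjusted p = 2.50e-06; adjusted p = 0.36 with an estimated correlation). Immediate early genes went both ways, 5 of 22 higher and 3 lower, in number the same adjusted over the list alone (camera adjusted p = 0.348): Klf4 rose from 11.8 ± 5.48 to 66.1 ± 19.1 CPM and Fos fell from 37.9 ± 6.22 to 13.3 ± 2.83 CPM. Proteasome subunit genes did so too, 4 of 30 higher and 5 lower, in number the same adjusted over the list alone (camera adjusted p = 0.348).

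The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. Counted with the real one, 1 of 10 splits gave as many genes higher as the real 2945, and the highest other gave 0; the same 1 and 0 held for the 2954 lower genes and the 1850 genes changed 2-fold. The other splits gave 13 to 552 genes at an unadjusted p under 0.05 by edgeR, and 0 to 66 changed genes by DESeq2. For camera with the preset correlation 5 of 10 splits called as many lists as the real 11, and the highest other called 14. Of splits that also parted all 3 pairs, the highest other called 10 lists and 0 genes. Every other split mixed the groups, so it kept part of their difference and put the rest into the spread within its sides. These counts therefore do not show what the tests give without a difference.

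The fall of cholesterol genes was weighed against 3 explanations. Removing the GC and length trend with the replicate block left the median log2 change at -1.78, against -1.79 before, so that trend is not its whole cause. Lost leukocyte transcripts cannot supply it unless those cells held far more cholesterol transcripts than marker transcripts, since the cholesterol list lost at least 7.74 times as many CPM as the leukocyte markers in each pair. A sterol excess would raise liver X receptor targets, and 8 of 11 fell and 1 rose (8 and 1 adjusted over the list alone). Blocked camera gave p = 4.26e-04 downward, and adjusted p = 0.44 with an estimated correlation. Camera also called lists in splits that mixed the groups, though these still held part of the group difference. A fall had been set in advance as the value against a sterol excess, but that did not allow for Scd1 and Srebf1, which are also in the fatty acid list, or for Apoe, Abca1, Abcg1 and Nr1h3, which macrophages express. Without these 2 of 5 fell and 1 rose, with a median log2 change of -0.044, so the test decides nothing about a sterol excess, which stays open. An effect of CPC on sterol regulation stays open too and was not tested.

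The rise of p53 targets was weighed against overlap with the integrated stress response, which also induces some of them. The 9 members listed as shared all rose, with a median log2 change of 1.25. Of the other 19, 12 rose and 1 fell, with a median of 0.49 (blocked camera p = 6.28e-05; p = 0.26 with an estimated correlation), so shared members are not the whole of the pattern. Removing the GC and length trend left the median of the full list at 0.67, against 0.69 before. An effect of CPC on p53 stays open and was not tested.

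The fall of leukocyte markers may come from fewer macrophages, from less carry-over at isolation or from repression within them. A loss of every contaminating cell type alike is argued against only as far as the epithelial and stromal markers come from such cells. Luteal and oocyte markers were not part of this comparison. Of 8 luteal markers, several of them steroidogenic, 6 fell, with a median log2 change of -2.42, and most oocyte markers were too low to test. The comparison therefore does not show that the leukocyte fall was particular to leukocytes. Whether granulosa cells express these markers was not tested. The 95% bootstrap intervals resampled the markers of a list as if independent, so they measure no spread between libraries. The upper end for the leukocyte median was -2.14, while the intervals for epithelial and stromal markers were -0.62 to 0.56 and -0.59 to 0.25. With the replicate block the leukocyte upper end was -2.13 and the epithelial and stromal lower ends -0.94 and -0.55, and the intervals also stayed apart without each replicate number of both groups, nearest without replicate 1 (-2.60 against -1.65 for epithelial markers). Epithelial markers were highest in replicate 1 of both groups, and their median depends on keeping that pair whole. Without CPC 1 alone, with control 1 kept, it was -2.40 (-2.86 to -1.27), overlapping the leukocyte interval (-4.04 to -2.41), while the stromal lower end was -1.50. With control 1 alone left out, the epithelial median was 0.72 (0.13 to 2.26). Both settings break the pair, so neither tells an effect of exposure from the high level of replicate 1. Summed leukocyte markers fell from 201 to 23.9, 253.7 to 14.3 and 328 to 38.7 CPM in pairs 1 to 3. Summed epithelial markers went from 412 to 473, 159.7 to 98.3 and 182.8 to 107.6 CPM, and the replicate block called 4 of 10 lower and 1 higher, so an epithelial loss stays open. Markers with over 3 counts per CPC library on average fell by unequal amounts (log2 changes of -4.30 to -0.83, with Cochran Q 9.43 times its degrees of freedom, where equal falls give about 1; the limit of 2 for calling falls unequal, and the rule that unequal falls alone settle nothing, were set after this value was seen, in place of a chi-square p-value that also called the falls unequal), but granulosa expression of a marker such as Cd68 would also make its fall smaller. Loss of 1 cell source and changes within it therefore cannot be told apart, and any difference in isolation would follow the groups.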
